A study of Mus musculus with 6 samples.

How the data were processed

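Genomic DNA of male germ cells was measured by whole-genome bisulfite sequencing, in which unmethylated cytosines are read as T and methylated cytosines stay C. Per the labels' protocols, Oct4-GFP positive germ cells were flow-sorted from the testes of individual mouse pups at postnatal day 2.5, about 10 ng of DNA per pup was treated with bisulfite after an unmethylated lambda phage DNA spike of 0.5%, and libraries were made with the Ovation Ultralow Methyl-Seq kit and sequenced as paired reads of 75 nt. The pups came from crosses between heterozygous parents on a mixed strain background. Groups were taken from the genotype label: Tex15WT (pups 8 and 9), Tex15HT (pups 7 and 18) and Tex15KO (pups 3 and 16), so each sample is a separate animal and n = 2 per group.

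The authors deposited 1 table for all 6 samples that gives, per the file headers, counts at each cytosine of a CpG: the coverage, the calls read as C and the calls read as T. These are raw counts, with the 2 strands of a CpG on separate lines. Per the submitters' processing notes, BSMAP, Bismark and methylKit were used on the mouse genome build mm9, with no role, order or version for these tools. Removal of PCR duplicates, the lambda conversion rate and other filters are not given in the sources used here. Tested on the values, coverage equalled C plus T calls at all cytosines (0 exceptions), and the calls of the 2 samples of each genotype summed to at least 3 at every cytosine. Of the 10025464 cytosines, 50718 had 3 or more calls in each of the 6 samples, and 38833 (0.387%) lay on the X chromosome.

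The total calls were 33019847 in Tex15WT 8, 33944329 in Tex15WT 9, 34236130 in Tex15HT 7, 40876698 in Tex15HT 18, 27495658 in Tex15KO 3 and 52935635 in Tex15KO 16. PCR reads without molecular identifiers are not independent molecules, so intervals given here (95%, Wilson) cover counting error only. The mean chi-square per 1 kb tile between the samples of a group was 1.93 for Tex15WT, 1.74 for Tex15HT and 7.54 for Tex15KO. It is near 1 for equal levels and independent reads, and PCR copies raise it as differences between pups do. Each pup was kept as a separate sample.

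A methylation level is the C calls over all calls, in percent. Calls were summed over strands and over 1 kb tiles of mm9, and a tile was tested with at least 3 CpGs and at least 10 calls in each of the 6 samples, which left 330110 tiles. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on methylated and unmethylated counts, with an intercept per sample, all 6 samples in 1 fit, and Benjamini-Hochberg adjustment over all tested tiles. A tile was called at an adjusted p under 0.05. In the fit of tiles with all 6 samples the estimated prior degrees of freedom were infinite, so the spread was shared over tiles. The p of a tile therefore does not measure how far the pups of a group differed at that tile. The comparisons were Tex15KO against Tex15WT, Tex15KO against Tex15HT, Tex15HT against Tex15WT, and Tex15KO against the mean of Tex15WT and Tex15HT. Differences of levels per sample were tested with a two-sided exact permutation test over the samples. With 2 against 4 samples there are 15 splits and the smallest p is 0.0667, and with 2 against 2 samples there are 6 splits and the smallest p is 0.333, so these tests cannot reach 0.05.

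Retrotransposons are repeated sequence, and their copies can be sought without an annotation from the distances between CpGs. Each run of 6 successive CpGs, strands summed, gave a pattern of 5 distances of up to 999 bp, read in either direction, and a pattern found at 10 or more places was called recurring. There were 662 such patterns, against 25 after the distances were shuffled. Patterns that adjoined each other at 50% or more of the places of the rarer were joined into 586 families, of which 581 had enough calls for the same edgeR test. A family is named by the distances, in bp, of its most frequent pattern. Such a family is a set of copies with the same CpG spacing and has no retrotransposon name here. The classes of sequence compared were chromosome types, the number of CpGs per tile, the tile level in Tex15HT, and CpGs with or without recurring spacing.

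Tests, thresholds, classes and all alternatives but those named below as added were chosen before the data were examined, except the reading of patterns in either direction, their upper distance and their joining into families, which were set later. The rule for named regions was also fixed then: among tiles called in Tex15KO against Tex15WT with both Tex15KO samples below, or both above, all 4 controls, the 10 largest decreases and the 5 largest increases, and among families the 5 largest decreases and the 3 largest increases. The alternatives fixed at that time were limma 3.58.1 on log2 ratios with a pseudocount of 1, Fisher's exact test on pooled counts, 30 calls, 10 CpGs, 5 kb tiles, a difference of 25 points, cytosines in the top 0.1% of coverage of any sample left out, autosomes only, thinning to the shallowest sample, higher coverage minimums for levels, 50 places for families, and leaving out each sample in turn. Added after seeing the data were the reduction of Tex15KO 3 to 1 call per cytosine, families without the top 0.1% of coverage, a count of tiles in which both Tex15KO samples lay over 30 points below all 4 controls, and tiles chosen with 1 sample per group and measured in the samples not used to choose them.

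The edgeR and limma scripts were tested on simulated data with 30000 tiles at the real depths, with the deepest tiles capped. The spread between simulated samples was set by hand and not taken from the data. For Tex15KO against Tex15WT, edgeR recovered 62 of 100 tiles lowered by 50 points and 13 of 100 lowered by 30 points, with 0 calls among unchanged tiles, and limma recovered 62 and 14 with 1 such call. In a simulation added after seeing the data, with the calls of Tex15KO 3 drawn as PCR copies, edgeR and limma both recovered 0 of 100 at either size in this comparison. With 10 times the calls and no copies, edgeR recovered 100 and 88, with 4 calls among unchanged tiles.

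Promoters, exons, introns and the fixed gene lists were left out, because the gene table at hand is of the assembly GRCm38.p6 and the calls are on mm9, and coordinates were not converted. For the same reason no tile is placed in a gene here. The Tex15 transcript and the targeted part of its locus were not analysed here, so the genotype labels could not be checked that way. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.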

Results

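Methylation of CpG cytosines was compared in sorted male germ cells of 6 mouse pups at postnatal day 2.5, with 2 pups each of the genotypes Tex15WT (wild type), Tex15HT (1 disrupted copy) and Tex15KO (both copies disrupted). Tex15 encodes a germ cell protein known to act with the PIWI pathway in silencing retrotransposons, and the study asks whether such repeated sequence is less methylated in its absence. Between 27495658 and 52935635 calls per sample covered the 10025464 cytosines of the table, at a median of 2 to 4 calls per covered cytosine in 5 samples. Tex15KO 3 differed in kind from the others: 74.4% of the cytosines had 0 calls there, against 1.71 to 10.2% elsewhere, and the covered ones had a median of 8 calls. Among cytosines with 6 to 10 calls, 96.5% had calls all alike in Tex15KO 3, against 57.8 to 68.3% in the other samples and 63.1% in Tex15KO 16.

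The first comparison asks whether repeated sequence lost methylation in Tex15KO germ cells, and was made over families of copies with the same CpG spacing. In 6 families, methylation was high in Tex15WT and Tex15HT and low in both Tex15KO samples. The family 4-5-15-4-12 (10 copies on 9 chromosomes or unplaced sequences) was methylated at 85.9% ± 1.71 in Tex15WT, 80.7% ± 2.71 in Tex15HT and 6.54% ± 1.06 in Tex15KO (SD, n = 2 each). The family 3-7-13-4-21 (50 copies) went from 82.7% ± 2.13 in Tex15WT to 13% ± 0.939 in Tex15KO, and 4-13-7-3-37 (23 copies) from 81.5% ± 1.59 to 12.9% ± 0.306. The family 7-7-5-4-29 (30 copies) lay at 91.7% ± 2.26 and 22.1% ± 0.831, and 4-5-7-7-35 (38 copies) at 86.5% ± 0.482 and 18.8% ± 2.52. In edgeR's test of Tex15KO against Tex15WT the adjusted p of these 5 was 6.15e-05 for 4-5-15-4-12, 1.08e-07 for 3-7-13-4-21, 2.57e-07 for 7-7-5-4-29, 1.78e-06 for 4-13-7-3-37 and 1.17e-07 for 4-5-7-7-35, each lower in 2 of 2 Tex15KO samples. The call held in limma (adjusted p 0.00881 to 0.0098) and with any 1 sample left out. Both Tex15KO samples had similar values in these families although their libraries differed, for example 12.3% in Tex15KO 3 and 13.7% in Tex15KO 16 for 3-7-13-4-21, from 1743 and 2774 calls.

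The loss was spread over the copies. In Tex15KO 16, 10 of 10 copies of 4-5-15-4-12 lay below 50%, 49 of 50 copies of 3-7-13-4-21, 25 of 30 copies of 7-7-5-4-29, 23 of 23 copies of 4-13-7-3-37 and 35 of 38 copies of 4-5-7-7-35. In the pooled controls, 0, 4, 0, 2 and 1 copies did. The copies with most calls lay on chromosome 6 at 9554121 to 9554162 for 4-5-15-4-12, on chromosome 12 at 96823787 to 96823872 for 3-7-13-4-21, on chromosome 13 at 40721615 to 40721668 for 7-7-5-4-29, and on chromosome 4 at 88022228 to 88022293 for 4-13-7-3-37 (all mm9). The 6th family, 4-11-5-6-5 (11 copies), lay at 78.1% ± 1.26 in Tex15WT, 59.2% ± 13.5 in Tex15HT and 16% ± 5.86 in Tex15KO. Its edgeR adjusted p was 0.0442, and the call was lost in limma (0.0549), without the top 0.1% of coverage (0.0588, with the level of every sample unchanged) and without any 1 of the 4 controls (0.307 without Tex15WT 8, 0.297 without Tex15WT 9, 0.075 without Tex15HT 7 and 0.0651 without Tex15HT 18). The family 2-6-2-4-13 (144 copies) fell less, from 85.9% ± 1.19 to 57.4% ± 4.22, with 60 of 143 copies below 50% in Tex15KO 16 (edgeR adjusted p 0.000306, limma 0.308).

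**Figure D1:**
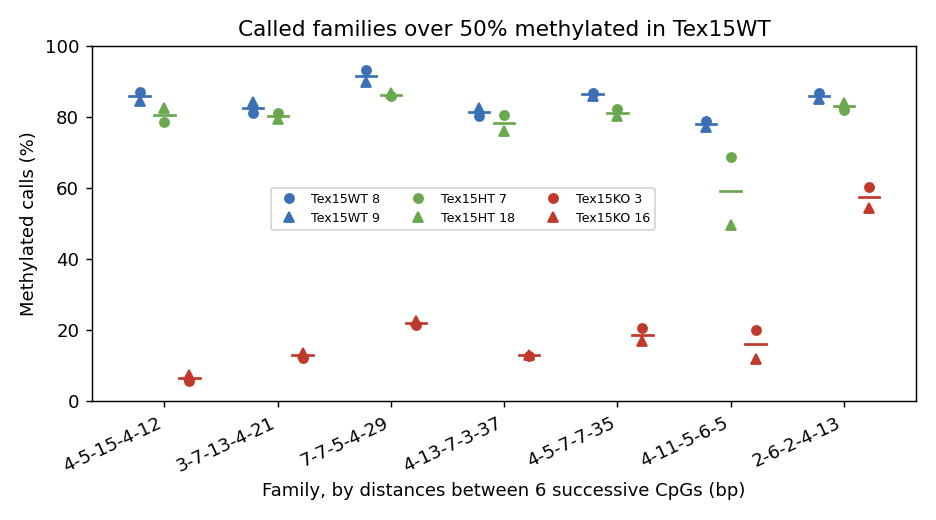
Methylation level (percent of calls, vertical axis) in each of the 6 samples for the 7 called families over 50% methylated in Tex15WT; points are samples, coloured by genotype, and short bars are group means (n = 2). Tex15KO samples lie between 5.79 and 22.7% in the first 6 families and at 54.5 and 60.4% in the family 2-6-2-4-13.

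Across the 581 families tested, edgeR called 14 lower and 0 higher in Tex15KO than in Tex15WT, with 39 lower and 9 higher at an unadjusted p under 0.05, and limma called 5 lower and 0 higher. Against Tex15HT, 10 families were lower and 0 higher (36 and 9 unadjusted, limma 6 and 0). Of the 14, 7 were methylated at under 20% in Tex15WT already. The family 2-2-3-2-6 (17 copies) lay at 12.3% ± 6.04 in Tex15WT, 18.3% ± 1.09 in Tex15HT and 0.444% ± 0.628 in Tex15KO, and its call (edgeR adjusted p 0.027) was lost without Tex15WT 8 (0.211). In the other 6, between 84.2 and 93.3% of calls came from a single copy of very high coverage. That copy lay within 17:39980001 to 39986000 for 3-7-2-4-5, 3-3-4-7-4 and 4-4-2-4-6, and within 16:11144001 to 11145000 for 2-3-3-2-6 and 3-3-2-6-3. Some families with large losses also had places within 2 kb of each other, so the 14 are not 14 separate losses. The call of each of the 6 was lost once the top 0.1% of coverage was left out. In 5 of these 6, every sample then lay at 1.95% or lower. The other one, 2-3-3-2-6, lost its call (adjusted p 0.852) but not its difference, with 9.36 and 22.3% in Tex15WT, 14.6 and 29.6% in Tex15HT and 0 and 6.84% in Tex15KO. Without Tex15KO 16 the count rose to 31, of which 23 were lower and 8 higher.

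The second comparison tested every 1 kb tile of Tex15KO against Tex15WT. The largest decreases took nearly fully methylated tiles to nearly unmethylated ones. The tile at 4:8412001 to 8413000 went from 97.0% ± 1.15 in Tex15WT and 88.6% ± 3.79 in Tex15HT to 1.85% ± 2.62 in Tex15KO (n = 2 each, at least 23 calls per sample, edgeR adjusted p 0.00452). The tile at 13:40721001 to 40722000, which holds a copy of the family 7-7-5-4-29, went from 92.8% ± 1.63 and 86.9% ± 2.60 to 10.4% ± 6.92, on at least 166 calls per sample (0.00132). Decreases of more than 90 points were also called at 17:22963001 to 22964000 (96.9% ± 4.33 to 1.47% ± 2.08), 11:7744001 to 7745000 (96.3% ± 5.24 to 0.962% ± 1.36), 4:70952001 to 70953000 (98.3% ± 2.44 to 3.13% ± 4.42), 10:56749001 to 56750000 (92.3% ± 2.01 to 0.595% ± 0.842) and 3:95210001 to 95211000 (93.2% ± 0.129 to 2.14% ± 3.03), with edgeR adjusted p between 0.0171 and 0.0419.

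The remaining tiles named by the rule were 13:7332001 to 7333000 (100% ± 0 to 19.6% ± 22.7), 13:100994001 to 100995000 (83.5% ± 15.9 to 3.39% ± 1.96) and 18:85124001 to 85125000 (74.9% ± 14 to 0% ± 0, from 72 and 70 calls). Each decrease was seen in 2 of 2 Tex15KO samples against 4 of 4 controls, which the naming rule required. The edgeR calls were lost with fewer controls. Of the 11 named tiles, counting the increase below, 11 lost the call without Tex15WT 8 (adjusted p 0.661 to 1), 11 without Tex15WT 9 (1 for each) and 10 without Tex15HT 7 or without Tex15HT 18. The exception without a Tex15HT sample, 13:40721001, was then at 0.0263 and 0.0211. The differences stayed large where calls were lost: without Tex15WT 8 or Tex15WT 9 the 10 decreases were between -65 and -99.0 points. Tex15HT samples do not enter these differences, so leaving 1 out could not change them. The 11 kept the call in limma (0.0149 to 0.0207), and 6 lost it when calls were thinned to the shallowest sample (adjusted p up to 0.0929). With 1 Tex15KO sample left out the 10 decreases were between -64.3 and -98.3 points, but both samples had been used to choose the tiles. The only called increase was at 8:49427001 to 49428000, with 8 and 3.57% in Tex15WT, 50 and 10.3% in Tex15HT and 100 and 100% in Tex15KO, from 24 and 35 calls (edgeR adjusted p 0.0377). At high coverage, tiles 11:3092001 to 3093000 and 11:3093001 to 3094000, singled out after their values were seen, lay at 66.6% ± 0.718 and 72.7% ± 1.07 in Tex15WT, 66.0% ± 0.699 and 71.5% ± 2.39 in Tex15HT, and 15.6% ± 1.08 and 27.3% ± 4.47 in Tex15KO, on at least 951 and 5097 calls. EdgeR called both and limma neither (adjusted p 0.445 and 0.582).

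In all, edgeR called 31 tiles lower and 1 higher of 330110 (4171 and 4779 at an unadjusted p under 0.05), and limma called 318 and 1, with 13 of the 31 among its calls. Tiles called by edgeR alone included 17:39983001 (limma adjusted p 0.606) and 3:5860001 (0.587), singled out after their values were seen. The 31 lay on 13 chromosomes or unplaced sequences, and 15 of them held recurring spacing. In Tex15WT, 15 were over 50% methylated and 11 were under 20%. Of the 31, 28 had both Tex15KO samples below all 4 controls, and 11 had at least 1000 calls in every sample. The decreases ran from -95.5 to -1.26 points. All 6 adjoining tiles of 17:39980001 to 39986000 were among the 31, so these are not 31 separate losses. The count depended on every sample: it was 11 tiles without Tex15WT 8, 10 without Tex15WT 9, 17 without Tex15HT 7, 18 without Tex15HT 18, 504 without Tex15KO 3 (502 of them lower) and 15769 without Tex15KO 16. With the top 0.1% of coverage left out edgeR called 0 tiles (4038 lower and 4655 higher unadjusted), and the 11 named tiles lost their call there, at a lowest adjusted p of 0.0598 over all tiles. Their differences hardly moved: they were unchanged in 9 of the 11, -80.3 points in place of -82.4 at 13:40721001 and -77.3 in place of -80.1 at 13:100994001.

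A count with no model, added after the data were seen, gives the extent of these losses. In 1505 of the tested tiles (0.456%) both Tex15KO samples lay over 30 points below all 4 controls, and in 64 tiles over 30 points above. The lower tiles averaged 81.2% ± 1.03 in Tex15WT, 78.7% ± 0.388 in Tex15HT and 14.5% ± 6.42 in Tex15KO. They formed 1437 regions, 1372 of them a single tile, and were found on each of the 19 autosomes, from 0.246% of tested tiles on chromosome 11 to 0.721% on chromosome 3. Recurring spacing was held by 116 of them (7.71%) against 1.25% of the other tested tiles (Fisher's exact test, two-sided, odds ratio 6.59, p 2.31e-52). This p counts each tile as a separate unit, so it does not measure the spread between pups. The tiles were also not matched on CpG number, which had a median of 9 in the lower tiles and 8 in all tested tiles. By any margin, both Tex15KO samples lay below all controls in 4.32% of tiles and above all in 8.24%. Samples that vary alike and have no ties would give 6.67% by chance. Tex15KO 3 did not vary like the others, so these shares cannot be read against that value. The other 14 ways to pick 2 of the 6 samples gave at most 178 lower tiles, for Tex15WT 9 with Tex15KO 3, and at most 35 without Tex15KO 3. Without Tex15KO 3 the count was 3562 and without Tex15KO 16 it was 17876.

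**Figure D2:**
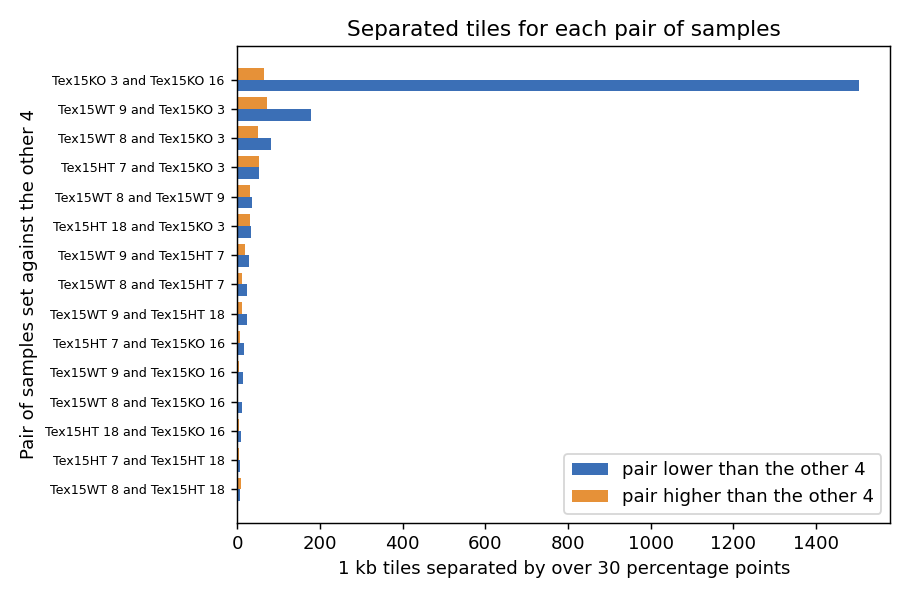
Number of 1 kb tiles (horizontal axis) in which a pair of samples lies over 30 percentage points below (blue) or above (orange) the other 4, for each of the 15 pairs (vertical axis). The Tex15KO pair gives 1505 lower tiles, and the next pair gives 178.

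Regions chosen in Tex15KO 16 were low in Tex15KO 3 too. In 4054 tiles, Tex15KO 16 lay over 40 points below Tex15WT 8 and Tex15HT 7, and in these tiles the samples not used for the choice averaged 28.8% in Tex15KO 3, 78.6% in Tex15WT 9 and 76.8% in Tex15HT 18. These means cover the tiles with 5 or more calls in the sample, which were 2737 in Tex15KO 3 (SD over tiles 35.7), 3934 in Tex15WT 9 (17.4) and 3969 in Tex15HT 18 (18.6). Over all tiles that could be chosen, Tex15KO 3 averaged 79.8%. Around the 3697 regions these tiles form, Tex15KO 3 lay at 26.0% within 0.5 kb of the centre and at 75.1% between 4 and 8 kb away, where Tex15WT 9 lay at 74.3% and Tex15HT 18 at 76.2%. The opposite choice gave another result: in 19544 tiles chosen in Tex15KO 3 against Tex15WT 9 and Tex15HT 18, Tex15KO 16 averaged 76.9%. The controls not used for this choice averaged 83.2% in Tex15WT 8 and 83.5% in Tex15HT 7. Over all tiles that could be chosen, the 3 averaged 79.0%, 79.0% and 79.7%, in that order.

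**Figure D3:**
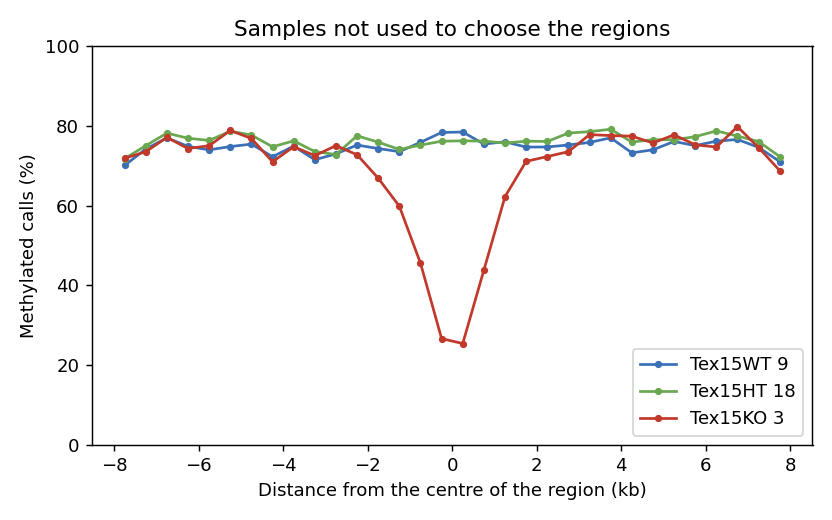
Methylation level (percent, vertical axis) in 500 bp steps of distance (kb, horizontal axis) from the centre of 3697 regions chosen in Tex15KO 16 against Tex15WT 8 and Tex15HT 7; each line is a sample that had no part in the choice. The line of Tex15KO 3 dips to 25.4% beside the centre and lies beside the control lines 4 to 8 kb away.

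Tex15KO was next set against the heterozygous pups. Of the tiles lower in Tex15KO than in Tex15HT, 3:36024001 went from 100% ± 0 in Tex15HT to 1.92% ± 2.72 in Tex15KO, 16:42985001 from 97.5% ± 3.54 to 0% ± 0, 11:109591001 from 91.1% ± 6.63 to 0.794% ± 1.12 and 2:150921001 from 81.2% ± 3.57 to 9.02% ± 2.91 (SD, n = 2, at least 12 calls per sample, singled out after their values were seen, edgeR adjusted p 0.00497 to 0.0285). Tiles 13:40721001, 11:3092001 and 11:3093001 were called by edgeR in this comparison as well, with Tex15HT at 86.9, 66.0 and 71.5%. Limma did not call 2:150921001 (adjusted p 0.0597), 11:3092001 (0.606) or 11:3093001 (0.780). EdgeR called 16 tiles lower, 4 of them also called by limma, and 3 higher, and the 3 higher ones, 2:98502001, 2:98506001 and 2:98507001, differed by 1.82, 1.86 and 2.28 points on at least 580187 calls per sample. The count of 19 fell without either Tex15HT sample and rose without either Tex15KO sample. Without Tex15KO 16, where the rise was largest, many of the calls were higher. The count was 0 without the top 0.1% of coverage (4069 lower and 2944 higher unadjusted), and limma called 207, 202 of them lower.

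Against both control groups, Tex15KO was lower in 125 tiles and higher in 2 (edgeR), and limma called 896 lower and 19 higher. A difference of at least 25 points was present in 112 of the lower tiles. Families showed the same direction, with 13 lower and 0 higher (41 and 18 unadjusted, limma 6 and 0). The count of 127 tiles fell without any single control sample and rose without either Tex15KO sample. Many of the calls without Tex15KO 16, where the rise was largest, were higher in Tex15KO. With the top 0.1% of coverage left out the count was 77, of which 76 were lower and 1 higher.

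The control groups were compared as well. No region with a loss like that of Tex15KO was called: 4 tiles were lower in Tex15HT than in Tex15WT, with differences of -3.13 points at 2:98506001, -2.89 at 9:35113001, -2.78 at 2:98502001 and -2.17 at 2:98507001, all on at least 185670 calls per sample. EdgeR called 0 tiles higher (620 lower and 1154 higher unadjusted) and limma called 0 in either direction (1458 and 3711 unadjusted). The 4 edgeR calls became 0 without Tex15KO 3 (5154 lower and 10443 higher unadjusted) and 0 without Tex15KO 16 (3320 and 6379). Of the families, edgeR called 0 (4 lower and 1 higher unadjusted) and limma 0. In the 1505 lower tiles Tex15HT lay -2.51 points from Tex15WT, against 1.35 points in the other tested tiles.

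Methylation over the whole table was not lower in Tex15KO. Of all calls, 64.8% ± 0.745 were methylated in Tex15WT, 64.3% ± 0.111 in Tex15HT and 67.0% ± 1.93 in Tex15KO. The difference was 2.22 points from Tex15WT (exact permutation test, two-sided, p 0.333) and 2.49 points from the 4 controls (same test, p 0.0667). Each p is the smallest its test can give. Averaged per cytosine, the levels were 75.1% ± 1.53, 76.5% ± 0.560 and 75.8% ± 0.280. Without Tex15KO 3 the difference in calls from Tex15WT was 0.853 points, without Tex15KO 16 it was 3.58 points. At cytosines with at least 5 calls in every sample it was -0.435.

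By class, tiles with 3 to 9 CpGs were methylated at 82.7% ± 1.69 in Tex15WT, 83.8% ± 0.519 in Tex15HT and 84.4% ± 0.742 in Tex15KO, and tiles with 10 to 19 CpGs at 48.7% ± 0.347, 46.7% ± 0.611 and 50.5% ± 2.01. CpG-dense tiles, with 20 or more, lay at 16.1% ± 0.0718, 15.8% ± 0.0913 and 13.8% ± 1.29. Their difference of -2.22 points between Tex15KO and Tex15WT (exact permutation p 0.333) was -1.31 without Tex15KO 3, -0.0641 without the top 0.1% of coverage and 0.209 per cytosine. From the 4 controls Tex15KO differed by -2.07 points of all calls there (exact permutation p 0.0667). CpGs with recurring spacing, as a class, lay at 40.5% ± 0.755, 38.4% ± 0.890 and 40.3% ± 0.177 of calls, a difference of -0.247 points between Tex15KO and Tex15WT. Per cytosine they lay at 25.3% ± 0.0207 in Tex15WT and 23.7% ± 1.38 in Tex15KO (-1.59), and without the top 0.1% of coverage at 25.5% ± 0.643 and 23.9% ± 3.03 (-1.58). CpGs without recurring spacing lay at 68.8% ± 1.15, 69.0% ± 0.419 and 70.7% ± 1.43. On the X chromosome the levels were 55.3% ± 0.0334, 53.9% ± 0.484 and 58.7% ± 5.85, with 62.9% in Tex15KO 3 and 54.6% in Tex15KO 16. By the level of the tile in Tex15HT, tiles over 80% lay at 90.3% ± 2.08 in Tex15WT and 91.9% ± 0.351 in Tex15KO, tiles of 20 to 80% at 44.8% ± 0.757 and 45.6% ± 1.49, and tiles under 20% at 6.11% ± 1.03 and 5.53% ± 0.510. The sign of each of these differences between Tex15KO and Tex15WT changed under at least 1 alternative. At cytosines with at least 5 and at least 10 calls in every sample it turned negative for tiles of 3 to 9 CpGs (-0.152 and -0.447 points), of 10 to 19 CpGs (-0.228 and -0.241), of 20 to 80% (-0.327 and -0.332) and of over 80% (-2.97 and -2.73) and for CpGs without recurring spacing (-0.806 and -0.917). Per cytosine, without the top 0.1% of coverage and without Tex15KO 3 it turned negative on the X chromosome (-1.91, -0.308 and -0.686) and for tiles of 20 to 80% (-0.726, -0.153 and -0.212). It turned positive without Tex15WT 9 for tiles under 20% (0.151) and at recurring spacing (0.287), and for patterns at 50 or more places (0.244). The exact permutation tests of 2 against 4 samples could not give a p below 0.0667 for any class. They therefore cannot show whether a class differed.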

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

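The tests of both patterns in this part were chosen after the results were seen. Mitochondrial DNA, which carries little or no CpG methylation and was part of the whole table above but not compared on its own, was read as methylated in 1.82% of calls in Tex15KO 3 (Wilson 95% interval 1.69 to 1.96%), above the 0.656 to 0.826% of the 4 controls and the 0.753% of Tex15KO 16.

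The same library stood apart at single cytosines. In Tex15KO 3, cytosines with 6 to 10 calls had calls all alike in 96.5% of cases, and in 0.708% a level between 20 and 80%, against 14.6 to 21.5% in the other samples. An effect of the genotype is argued against by Tex15KO 16, where calls were all alike at 63.1%, within the 57.8 to 68.3% of the controls. Many PCR copies of few starting molecules may account for the pattern: the calls at a cytosine would then repeat 1 molecule, as the 96.5% and the 74.4% of cytosines with 0 calls would have it. In the edgeR fit, the common dispersion was 0.347 with all samples, 0.112 without Tex15KO 3 and 0.121 with Tex15KO 3 reduced to 1 call per cytosine.

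As a source of the 1505 tiles lower in both Tex15KO samples, more complete bisulfite conversion would lower the surroundings as well, but 4 to 8 kb from their 1437 regions Tex15KO lay at 73.7% ± 0.658, a difference of -1.28 points from the 4 controls (75.0% ± 1.29). PCR copies in Tex15KO 3 would leave it at its usual level in the 4054 tiles chosen with Tex15KO 16 and 2 controls, without Tex15KO 3, where it averaged 28.8% over the 2737 with calls enough, against 79.8% over all eligible tiles. The same 28.8% argues against strain variants at single CpGs, which would spare most CpGs of a tile. The Tex15KO pair was 1 of 15 ways to pick 2 of 6 samples, with 1505 lower tiles against at most 178 for the other pairs and 35 for those without Tex15KO 3, and 15 splits are too few for a share under 0.05. A loss of methylation that goes with the Tex15KO genotype is a candidate explanation, but strain differences of whole regions cannot be told apart from it, because the labels give a mixed background and neither the litter nor the strain make-up of each pup.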

How the results depend on the processing

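The alternatives chosen after the data were seen are 1 call per cytosine in Tex15KO 3, families without the top 0.1% of coverage, and all settings of the count of separated tiles; the rest were planned. Counts of called tiles are given for Tex15KO against Tex15WT, Tex15KO against Tex15HT, Tex15HT against Tex15WT, and Tex15KO against both, in that order. They were 32, 19, 4 and 127 with edgeR and 319, 207, 0 and 915 with limma. Fisher's exact test, which ignores the spread between pups, gave 32844, 26868, 1923 and 41127. Its calls for Tex15KO went both ways: 15199 lower and 17645 higher against Tex15WT, 15920 and 10948 against Tex15HT, and 22817 and 18310 against both. The 4 counts were 53, 44, 5 and 98 with 30 calls per sample and 51, 29, 4 and 149 with 10 CpGs. In 5 kb tiles they were 66, 55, 7 and 243, and with a difference of 25 points 20, 9, 0 and 113. Without the top 0.1% of coverage they were 0, 0, 0 and 77, where the unadjusted edgeR counts for Tex15HT against Tex15WT were 538 lower and 1097 higher, and the cause was not tested. With 1 call per cytosine in Tex15KO 3 they were 760, 613, 0 and 1102 (for the 0, unadjusted 2807 lower and 4978 higher). Leaving out 1 sample gave 10 (without Tex15WT 9) to 15769, 7 (without Tex15HT 18) to 15764, 0 (without Tex15KO 3 or 16) to 5, and 13 (without Tex15HT 18) to 22153, the highest of the first, second and last being without Tex15KO 16. The lone sample is then assumed to vary like the other groups. Without Tex15KO 16 the calls of Tex15KO against each control group and against both went in both directions. Without Tex15KO 3 the 4 counts were 504, 395, 0 and 896. Autosomes alone and thinning kept all 4 counts within 1.5 times, but thinning ended the call of 6 of the 11 named tiles. For the 11 named tiles, 75 of 134 alternatives kept the call, 59 lost it and 0 reversed it.

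The difference in level between Tex15KO and Tex15WT, 2.22 points, was 0.65 per cytosine, 0.902 without the top 0.1% of coverage, -0.435 and -0.475 at cytosines with at least 5 and 10 calls in every sample, and 0.853 (without Tex15KO 3) to 3.58 (without Tex15KO 16) with 1 sample left out. At recurring spacing it was -0.247, then -1.59 per cytosine and -1.58 without the top 0.1% of coverage, and -0.781 (without Tex15WT 8) to 0.287 (without Tex15WT 9) with 1 sample left out; the cause was not tested. Called families numbered 14, then 5 with limma, 3 of the 19 at 50 or more places, where fewer could be tested, 7 without the top 0.1% of coverage, and 11 to 31 (without Tex15KO 16) with 1 sample left out. Separated tiles numbered 1505, then 187 with 30 calls and 595 with 10 CpGs, where fewer were tested, 591 by over 50 points, and 1747 to 17876 (without Tex15KO 16) with 1 sample left out, where fewer samples have to be separated. They numbered 1310 with 1 call per cytosine in Tex15KO 3. In the simulated data, depth and PCR copies limited what was called. Without copies edgeR recovered 62 of 100 tiles lowered by 50 points and 13 of 100 lowered by 30 against Tex15WT, and 90 and 40 against both control groups. With Tex15KO 3 drawn as PCR copies it recovered 0 and 0, and 5 and 0. The simulation assumes such copies and does not show that Tex15KO 3 holds them. No paired analysis was possible because the groups share no pup numbers. The promoter and gene list comparisons and their alternatives were not run.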

Other observations

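The tests and counts in this part were chosen after the results were seen, except the edgeR calls without Tex15KO 3, which were planned. Some families with large losses had CpG distances in common: 3-7-13-4-21 and 4-13-7-3-37 share the distances 3, 7, 13 and 4, and 7-7-5-4-29 and 4-5-7-7-35 share 4, 5, 7 and 7. Of the 23 places of 4-13-7-3-37, 9 lay within 2 kb of a place of 3-7-13-4-21, and 5 of the 10 places of 4-5-15-4-12 lay within 2 kb of a place of 3-7-13-4-21. The 6 families that fell by more than 50 points cover 140 places in all, with places within 2 kb of each other counted once. In 330 tiles called lower without Tex15KO 3 that had 10 or more calls in it, Tex15KO 3 lay below all 4 controls in 319 (96.7%), against 20.9% of other tiles of similar level, with means of 14.6% in Tex15KO 3, 7.44% in Tex15KO 16 and 79.6% in the controls.

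Among stretches of tiles with at least 1000 calls in every sample, Tex15KO differed from Tex15WT in either direction. The difference ran from -45.4 points at 11:3093001, given above, to 7.38 at 15:74917001 and 9.21 at 2:5300001. The last had 29.3% in Tex15KO 3 and 6% in Tex15KO 16. At 2:98502001 to 98508000, where 1 cytosine reached 974994 calls in a sample, the level was 39.6% ± 1.06 in Tex15WT, 37.1% ± 0.975 in Tex15HT and 39.2% ± 0.127 in Tex15KO, and at 9:3000001 to 3039000 it was 36.6% ± 1.20, 34.2% ± 0.929 and 36.5% ± 0.00485 (SD, n = 2). At 17:39980001 to 39986000 it was 8.31% ± 1.46, 7.71% ± 2.15 and 4.02% ± 1.20, and at 3:5860001 to 5861000 it was 10.7% ± 3.54, 8.47% ± 3.41 and 2.58% ± 0.834. At 8:19785001 to 19786000, which was less deep (at least 406 calls per sample), the controls varied widely, at 46.0% ± 23.1 in Tex15WT and 29.8% ± 14.6 in Tex15HT, and Tex15KO lay at 1.24% ± 0.695. On the part of the X chromosome in the table, 22 of 289 tested tiles (7.61%) were lower in both Tex15KO samples by over 30 points, against 0.449% of autosomal tiles (Fisher's exact test, two-sided, odds ratio 18.3, p 4.41e-20). This p counts each tile as a separate unit, but all 22 X tiles rest on the same 2 Tex15KO pups. It does not measure the spread between pups. The X tiles were deeper, with a median of 18 calls in the shallowest sample against 15, and of 45 against 34 in Tex15KO 16. Autosomal tiles matched on the calls in the shallowest sample gave 0.464%. Such matching cannot show whether this part, 0.387% of the cytosines, stands for the whole X chromosome. These 22 averaged 78.6% ± 1.15 in Tex15WT, 79.8% ± 2.38 in Tex15HT and 14% ± 2.00 in Tex15KO, and 3 of them held recurring spacing.

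In the 1505 tiles lower in Tex15KO, Tex15HT lay below Tex15WT, at a difference of -2.51 points, with both Tex15HT samples below both Tex15WT samples in 24.2% of tiles and above in 11.1%. In the other tested tiles the difference was 1.35 points, within the spread of the Tex15WT samples (77.0 and 74.9%). A lower level of the Tex15HT libraries throughout would cancel within a library, but the level at the lower tiles minus that at the other tested tiles was 5.18 ± 0.442 points in Tex15WT and 1.32 ± 0.126 in Tex15HT (SD, n = 2), a difference of -3.86, and -5.21 against other tiles of similar level. Tex15HT also lay below Tex15WT in the deep sequence on chromosomes 2 and 9 given above, where Tex15KO did not fall, so a lower level in part of the sequence that has nothing to do with the losses in Tex15KO may also contribute. That 1 copy of Tex15 may leave a small part of these regions unmethylated is a hypothesis that cannot be told apart from differences between pups, because 2 against 2 samples cannot give an exact permutation p under 0.333.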
